A study of Caenorhabditis elegans with 2 samples.

How the data were processed

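LAG-1 is the CSL-type DNA-binding protein that carries Notch signals from the receptors LIN-12 and GLP-1 into the nucleus of Caenorhabditis elegans. Per the labels, its own gene was tagged by CRISPR with TY1, EGFP and 3xFLAG, whole worms were synchronised as starved L1 larvae and collected as young adults at 62 hours, and chromatin sheared by sonication was precipitated with an antibody to GFP. The series holds 1 group of 2 biological replicates, numbered in the labels, so no groups could be compared. Comparisons are between sets of peaks, candidates or genes, and the p-values describe these replicates.

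The values are those of peak lists on the ce11 assembly, made from reads of the precipitated DNA and of a control, per the notes deposited with each replicate. The aligner, the peak caller and their versions are not given in the sources used here, and the control's own reads were not analysed here. The deposited score of each peak is a whole number that follows the irreproducible discovery rate (IDR), the estimated share of false pairings between 2 ranked lists, and the lowest score in the thresholded lists was 830, the value at an IDR of 0.01. The deposited signal is the peak caller's own strength per peak over the control, in a unit that no header names, and it was used only to describe and rank peaks within a list. The deposited −log10 values of the ranked lists give the global IDR of each peak, and those of the thresholded lists give the caller's own false discovery rate.

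The main list was the deposited conservative list, which compares the replicates with each other. The authors' other series list, per the values, follows a ranking of pooled reads, and each replicate has a list of its own, made within that replicate. Entries that shared at least 1 bp were merged and the strongest gave the summit, which turned 291 entries into 289 regions, called peaks here. The replicate ranking held 125458 candidates. Background candidates were the 124955 that missed the threshold and touched no thresholded list. The ranking also held 100 entries past the threshold that the conservative list leaves out, and these were kept out of the background. The filter that removed them is not named in the sources used here. The files used hold no read totals, so depth is unknown, and no interval covers the error of a peak's signal. Intervals of shares are Wilson intervals at a confidence level of 95% and cover counting error only.

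Sequence came from the NCBI assembly WBcel235, which is ce11, and gene models from Ensembl release 115. Every peak lay inside the matching chromosome. The LAG-1 site was RTGGGAA on either strand within 100 bp of the summit. For motif tests each peak had 10 control candidates, drawn without replacement from the same location class and within 3 percentage points of GC content. Promoters ran from 500 bp upstream to 100 bp downstream of any protein-coding transcript's 5' end, and summits outside them were called exonic, intronic or intergenic. A gene had a peak if a summit lay between 2000 bp upstream of its 5' end and its 3' end. Shares were compared by 2-sided Fisher exact tests. Medians were compared by 2-sided permutation tests with 100000 resamples. Gene lists were compared by 2-sided permutation with 100000 random lists matched on decile of gene span. Adjusted p-values follow Benjamini and Hochberg within each family of tests (8 motifs, 15 gene lists, 6 chromosomes, 4 locations). The work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

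On simulated data with 289 peaks drawn from the candidates, the motif test called 5 of 100 draws with no planted difference. It called 80 of 100 draws with a planted site share of 10% and 100 of 100 at 15%. A planted share was held exactly in each draw, and controls in these simulations were drawn without matching. The counts therefore do not give the power of the matched test. The list test called 1 of 100 random lists of 76 genes and all 100 lists that held 10 genes with a peak. It called 3 of 100 lists of 5 genes with 1 planted peak, and all 100 lists of 28 genes with 3 planted. These calls used an unadjusted p under 0.05 and fixed planted counts. They therefore do not give the power of the test after adjustment over 15 lists. The median test called 7 of 100 draws with no difference.

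The tests, the lists of genes, the alternatives and the rule for named genes were fixed before the data were examined. The rule named 3 kinds of gene. The first kind comprised members of the Notch pathway, GLP-1 target, LIN-12 target and REF-1 family lists with a peak, and sygl-1, lst-1, lag-1, lin-12 and glp-1 in any case. The second kind comprised the gene with the nearest 5' end at each of the 20 strongest peaks. The third kind comprised up to 4 members of each other list with the highest signal. The other lists covered anchor cell and vulval regulators, germline stem cells and meiosis, intestine, body wall muscle, neurons, hypodermis, pharynx, gonadal sheath and spermatheca, heat shock, ribosomal proteins and histones. A listed name in the LIN-12 target list and 1 in the heat shock list had no match in the annotation and were left out. Alternatives covered the pooled list, each replicate's own list, no merging, windows of 50 and 200 bp, shorter and longer motifs, other controls, other overlap rules, other promoter spans and other rules for assigning genes.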

Results

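LAG-1 binding was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) of an EGFP-tagged LAG-1 expressed from its own locus in whole young adult worms at 62 hours, in 2 biological replicates of 1 group. LAG-1 is the nuclear effector of Notch signalling, which in the adult acts through GLP-1 in the germline and LIN-12 in somatic tissues. Depth per replicate is unknown from the files used. Coordinates are on ce11.

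LAG-1 ChIP gave 289 peaks that passed an IDR of 0.01 between replicates. The strongest lay in an intron of pxn-1, which encodes a peroxidasin of the extracellular matrix, at V:8500458 to 8500693, with a signal of 192.2 (the authors' peak caller value). The next strongest lay 459 bp downstream of the 5' end of K08F11.1, outside its annotated span (166.7), over the snoRNA gene C51F7.4 in an intron of frm-7, where the nearest 5' end was that of F55C5.17 (165.8), and in an intron of cmk-1, nearest to ccm-2 (164.8). Peaks 251 bp upstream of mog-4, a germline sex determination helicase gene, 318 bp upstream of cnk-1, a scaffold gene of Ras signalling, and 892 bp upstream of cbp-1, which encodes the CBP/p300 acetyltransferase, had signals of 163.0, 138.2 and 122.1. The peak 639 bp upstream of rpa-2, which encodes a subunit of replication protein A, had a signal of 128.8, and that 61 bp upstream of tasp-1 had 129.6. The remaining peaks among the 20 strongest were nearest to W02H3.3, F56G4.6, K07D4.2, Y54F10AM.8, F58D12.3, rpl-3, C36E6.8, F20B6.9, T27A8.7, F55G7.5 and M02F4.2, with signals from 125.7 to 162.6. Of these 20 peaks, 6 were on X, 5 were in promoters and 1, that near T27A8.7, held a LAG-1 site. The site share over all 289 peaks was 6.92%, so 1 among 20 shows no lack of sites. The median signal was 66.4 over all 289 peaks and 19.3 over background candidates.

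The 20 strongest peaks were all in replicate 2's own list and 18 were also in replicate 1's, the exceptions being those near Y54F10AM.8 and M02F4.2. At pxn-1 the signal was 87.9 in replicate 1 and 100.9 in replicate 2. The own lists held 47 and 77 peaks and shared 29, where 0.0301 would be shared by chance among 120299 merged candidates (Fisher exact test, 2-sided, p = 2.5e-83). Of the 289 peaks, 215 were in neither own list. Across the 289 peaks, which are not independent replicates, the signals in the compared lists had a Spearman rho of 0.241. The peak caller's own false discovery rate was 0.180 at its smallest in the conservative list, so that 0 entries passed 0.05 by that measure.

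**Figure D1:**
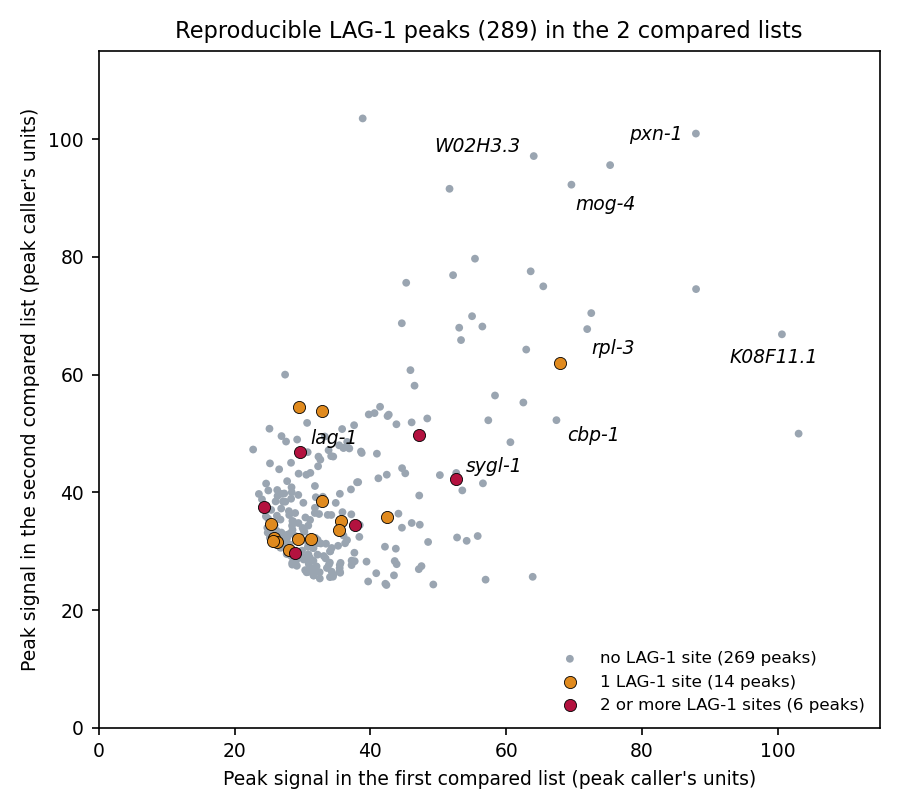
Signal of each of the 289 peaks in the first compared list (x axis) and in the second (y axis), in the peak caller's units, with 1 point per peak coloured by its number of LAG-1 sites within 100 bp of the summit. The signals rose together only loosely (rho 0.241), and the 6 peaks with 2 or more sites, among them sygl-1 and lag-1, did not have the highest signals.

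Among Notch genes, sygl-1 had the strongest peak. This gene is a direct GLP-1 target that acts with lst-1 to maintain germline stem cells. Its peak at I:12483725 to 12483960 had its summit in the 5' UTR, 34 bp downstream of the gene start, with a signal of 100.3 and an IDR of 0.00148. It was in both replicates' own lists, with signals of 52.6 and 42.3. All 4 LAG-1 sites near the summit read GTGGGAA, with starts at 12483747, 12483811, 12483827 and 12483843, of which the last 3 lay in the 5' UTR and the first upstream of the gene. A peak at IV:6097079 to 6097314 lay in an intron of lag-1 itself, 1790 bp downstream of the gene start, with a signal of 75.9, an IDR of 0.00315 and 2 GTGGGAA sites at 6097175 and 6097190. It was in replicate 2's own list (46.8) and not in replicate 1's.

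The Notch pathway list had peaks at 3 of 28 genes, namely lag-1, dos-3 and epn-1, where 0.455 was expected (permutation p = 0.0196, adjusted p = 0.147 over 15 lists). At dos-3, which encodes a DOS-domain co-ligand, the peak lay in the coding sequence (III:835957 to 836192, signal 79.9), and at epn-1, which encodes the endocytic adaptor epsin, there were 2, at 460 bp upstream (X:14818856 to 14819091, signal 69.6) and in an intron (X:14816700 to 14816935, signal 61.3). The peaks at dos-3 and epn-1 held 0 LAG-1 sites. With peaks kept only at an IDR of 0.005 or below, a setting chosen after the data were seen, the same count of 3 had an adjusted p of 0.0213. The GLP-1 target list had a peak at 1 of 5 genes, sygl-1 (adjusted p = 0.631, permutation test), and a list of 5 with 1 peak is called rarely by this test. The LIN-12 vulval target list (8 genes) and the REF-1 family list (6 genes) had 0 genes with a peak. Only 0.181 and 0.0585 were expected, so these counts of 0 could not show a depletion.

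The other fixed genes missed the threshold. Candidates were searched from 2000 bp upstream to the 3' end of each gene. At lst-1 the strongest in this span lay 181 bp upstream of the gene start (I:10588202 to 10588437) and held 4 GTGGGAA sites, but its signal was 29.2 and its IDR 0.180. Outside the rule for named genes, the strongest candidate at mir-61, a LIN-12 target microRNA gene, lay 161 bp upstream. It held 2 GTGGGAA sites, with a signal of 42.7 and an IDR of 0.0753. The receptor genes lin-12 (39.3, IDR 0.0650) and glp-1 (35.9, IDR 0.140) had candidates with 0 sites. Over the 45 genes of the Notch pathway, GLP-1, LIN-12 and REF-1 lists, sygl-1, lag-1, lst-1 and mir-61 were the 4 whose strongest candidate held 2 or more sites.

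**Figure D2:**
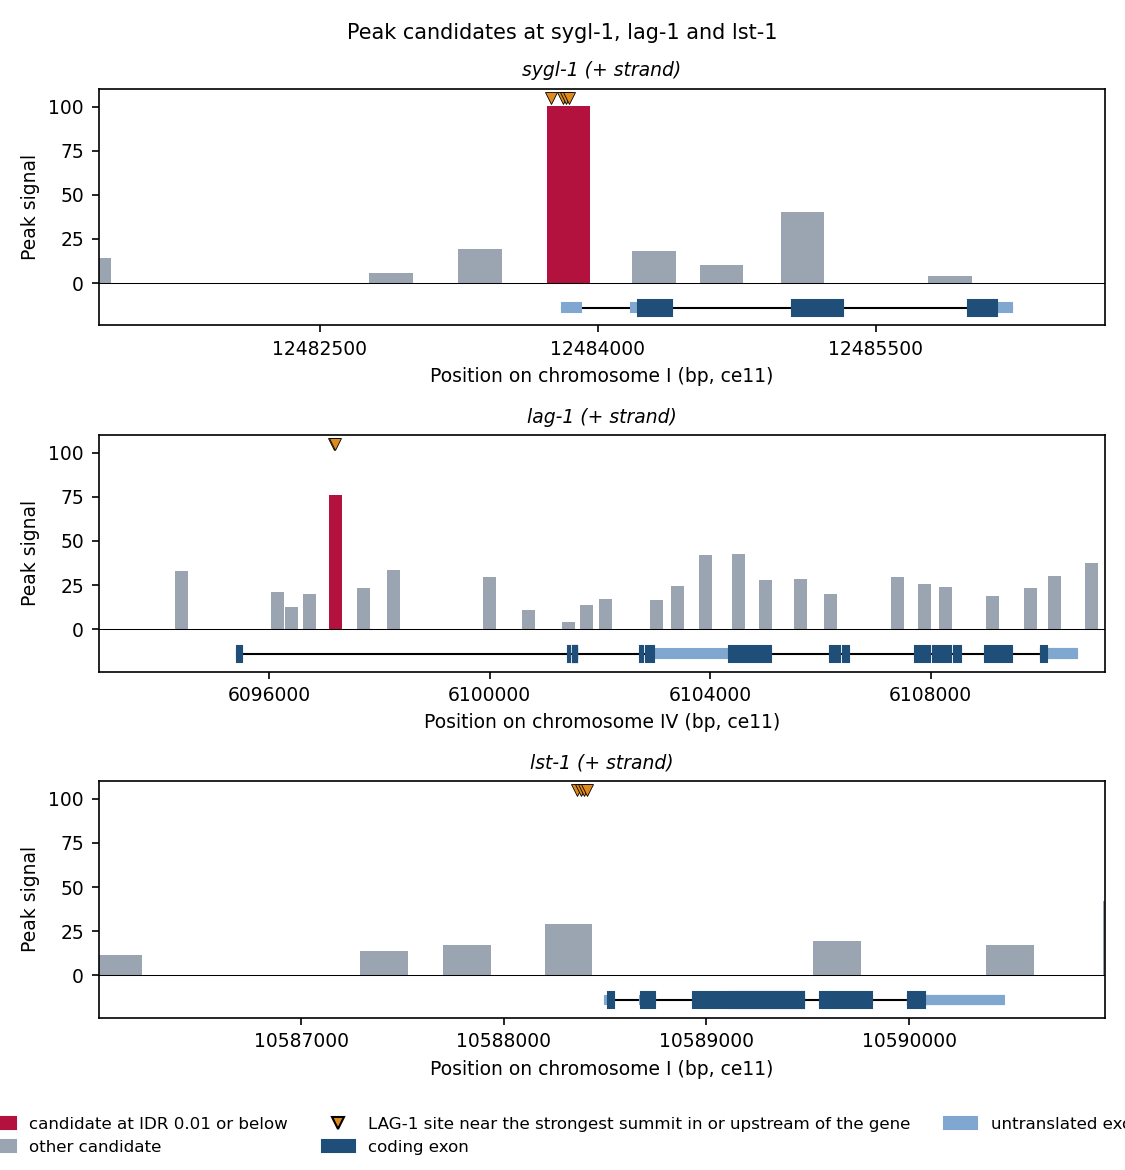
Peak candidates of the replicate ranking at sygl-1, lag-1 and lst-1, with position in bp on ce11 (x axis) and signal in the peak caller's units (bar height), above the gene models. Candidates at an IDR of 0.01 or below are red, and triangles mark the LAG-1 sites within 100 bp of the strongest summit between 2000 bp upstream and the 3' end of each gene: 4 at sygl-1 (signal 100.3), 2 at lag-1 (75.9) and 4 at lst-1 (29.2). The candidate cut by the right edge of the lst-1 panel (42.3, IDR 0.0834) lay outside that span.

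The LAG-1 site asks whether the peaks as a set carry the sequence LAG-1 is known to bind. RTGGGAA lay within 100 bp of the summit in 20 of 289 peaks (6.92%, 95% Wilson interval 4.52 to 10.4) and in 193 of 2886 matched controls (6.69%), an odds ratio of 1.04 (0.609 to 1.68, Fisher exact test, 2-sided, p = 0.902). The site ranked 152 among its 420 rearrangements by ratio of peaks to controls. Within 500 bp the nearest site was a median of 215.5 bp from the summit in peaks and 223 bp in controls (permutation test, p = 0.736). Peaks with a site had a median signal of 66.5 and those without 66.4 (permutation test, p = 0.982). In simulations with exact planted shares and unmatched controls, a share of 10% was called in 80 of 100 draws. Smaller shares were not simulated, and the power of the matched test is unknown. Of the 7 other motifs, 0 passed after adjustment and only GAGAGA passed unadjusted, at 22.5% of peaks and 17.1% of controls (Fisher exact test, p = 0.0233, adjusted p = 0.187). The GATA, E-box, E2F, forkhead, AP-1 and GC box motifs had adjusted p-values from 0.888 to 1.0.

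Ribosomal protein genes carried more peaks than matched genes. Peaks lay at 10 of 76 ribosomal protein genes where 0.881 was expected (permutation, adjusted p = 3e-04, the smallest that 100000 resamples could give over 15 lists). The strongest were 265 bp upstream of rpl-3 (139.6), 345 bp upstream of rpl-15 (101.4), 289 bp upstream of rpl-20 (101.1) and 426 bp upstream of rpl-35 (90.9). The 10 genes shared 9 peaks, since rps-14 and rpl-36 lie side by side, and 0 had a LAG-1 site. At the share of 6.92% over all 289 peaks, 0 among 9 shows no lack of sites. For 7 of the 10 the peak lay in a promoter, which could be that of a neighbouring gene. At rpl-43, 1 of these, the summit lay 772 bp upstream, beyond the 500 bp span of its own promoter. In the own lists of replicates 1 and 2 the count was 3 and 4, each past the threshold (permutation, adjusted p = 0.00540 and 0.00390). Among heat shock genes hsp-60, which encodes a mitochondrial chaperonin, was the 1 of 12 annotated loci with a peak (66.4), and among neuronal genes unc-104, a kinesin gene, was the 1 of 10 (54.7), each with an adjusted p of 1.0. Lists for anchor cell and vulval regulators (11 genes), germline stem cells and meiosis (20), intestine (13), body wall muscle (9), hypodermis (10), pharynx (6), gonadal sheath and spermatheca (7) and histones (72 annotated loci) had 0 genes with a peak, each with an adjusted p of 1.0. From 0.134 (hypodermis) to 0.955 (histones) were expected in each, so these counts of 0 could not show a depletion. Over the genome 297 of 19973 protein-coding genes (1.49%) had a peak.

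Promoters held 78 of the 289 summits (27%, interval 22.2 to 32.4) against 14.5% of background candidates, an odds ratio of 2.19 (1.66 to 2.85, Fisher exact test, 2-sided, adjusted p = 1.3e-07). Intergenic summits were also more frequent (35.6% against 27.9%, adjusted p = 0.00469), and exonic (18% against 30.3%, adjusted p = 5e-06) and intronic ones (19.4% against 27.3%, adjusted p = 0.00305) less frequent, all by Fisher exact tests. X carried 80 peaks (27.7%, interval 22.8 to 33.1) against 19.6% of candidates, an odds ratio of 1.57 (1.19 to 2.04, Fisher exact test, adjusted p = 0.00633), and no autosome passed (smallest adjusted p 0.307). Neither replicate's own list alone passed for X (26% and 25.5%, exact p = 0.195 and 0.356), and replicate 2's list passed for promoters where replicate 1's did not (23.4%, p = 0.0943). Within 500 bp of a tRNA gene lay 21 summits (7.27%, interval 4.80 to 10.9) against 0.679% of candidates, an odds ratio of 11.5 (6.94 to 18, exact p = 2.9e-15). Against controls matched on GC content and location, a comparison chosen after the data were seen, it was 6.03 (3.3 to 10.7, 1.28% of controls). In replicate 1's own list alone the share was 4.26% (exact p = 0.0409), and in replicate 2's 7.79%. Of these 21 peaks 16 were on X, which holds 276 of the 612 annotated tRNA genes. Mean GC content within 100 bp of the summit was 46.7% in peaks and 38% in all background candidates. Location shares were compared without matching on GC content, so its part in the promoter excess was not tested.

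**Figure D3:**
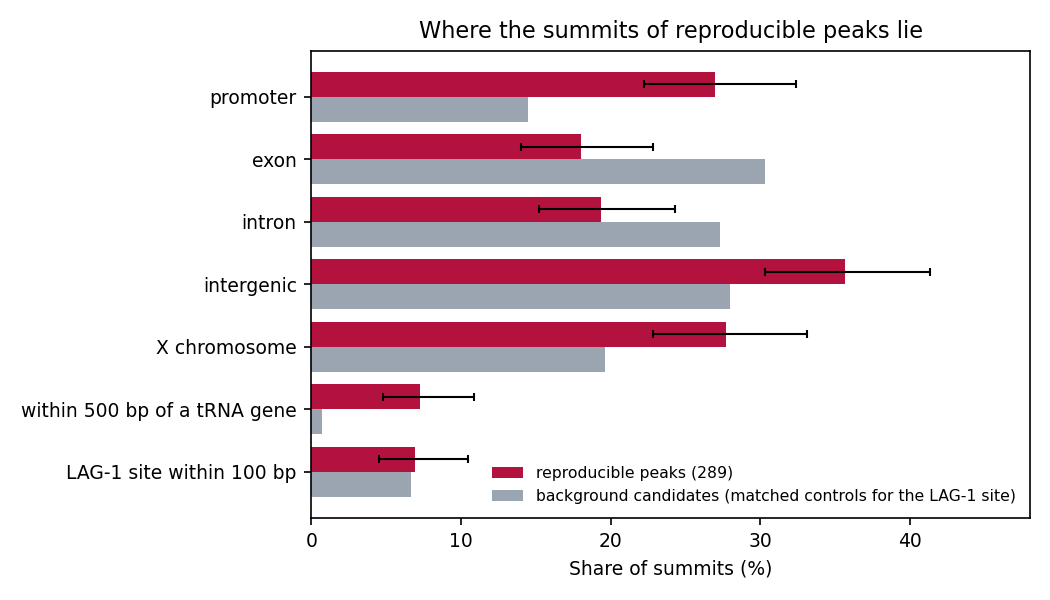
Share of summits (x axis, %) in each location class, on X, near a tRNA gene and with a LAG-1 site, for the 289 peaks (red, error bars are 95% Wilson intervals) and for background candidates or, for the LAG-1 site, matched controls (grey). Promoters (27% against 14.5%), X (27.7% against 19.6%) and tRNA genes (7.27% against 0.679%) exceeded the background, and the LAG-1 site (6.92% against 6.69%) did not.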

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

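All tests in this part were chosen only after the result was seen. The design has 1 group, so no explanation by a difference between groups of samples was tested.

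The replicate ranking held 100 entries past the threshold that the conservative list leaves out, a signal in data outside the main comparisons. The highest of them, at X:15810977 to 15811159, had a signal of 2465, against 192.2 for the strongest of the 289 peaks. Repeated sequence was the first explanation tested: 91 of the 100 left-out regions were repeat-masked over more than 50% of the bases within 100 bp of the summit, against 13.1% of the 289 peaks, an odds ratio of 66.8 (Fisher exact test, 2-sided, interval 29.9 to 161), which is what that explanation needs. LAG-1 sites inside repeats were also more frequent than in repeats at large, at 22% of the 91 masked regions and 5.25% of masked candidates, an odds ratio of 5.08 (2.92 to 8.47). Copies of a repeat are not independent, and left-out regions with a site had no detectable difference in signal from those without (medians 121.0 and 114.3, permutation p = 0.713), so whether LAG-1 occupies these repeats stays open.

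The LAG-1 site was not more frequent in peaks than in controls. Peaks of another origin may hide an excess, but without the peaks within 500 bp of tRNA, snoRNA or snRNA genes, in repeats or with a dosage compensation motif, the remaining 198 peaks had sites in 6.06% against 6.93% of controls, an odds ratio of 0.866 (0.429 to 1.60). Weakly bound control windows could also hide one, but against matched candidates of below-median signal the odds ratio was 0.921 (0.542 to 1.49). Both intervals exclude a doubling of the odds, which argues against both explanations for an excess of that size. A smaller excess, and peaks bound without a direct site, stay open. So does whether the peaks depend on LAG-1, since no ChIP from worms without the tag was analysed here.

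The excess of peaks on X was weighed against composition, tRNA genes and dosage compensation motifs. Against controls matched on GC content and location the odds ratio was 1.51 (1.13 to 1.99), which argues against composition as the whole cause. Without windows that hold the dosage compensation motif core GCGCAGGG it was 1.38 (1.03 to 1.81), which argues against exact cores near the summit as the whole cause. Only this exact word within 100 bp of the summit was searched, so the part of dosage compensation sites at large stays open. Without peaks and candidates near tRNA genes the odds ratio was 1.30 (0.963 to 1.73), an interval that holds both 1 and the full value of 1.57. So tRNA genes cannot be told apart from another origin of the excess with this number of peaks. Of the 80 X peaks, 16 lay near tRNA genes and 10 held the core. These classes were taken out separately and never together, so whether they jointly account for the excess was not tested.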

How the results depend on the processing

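The tests at an IDR of 0.005, with the left-out entries kept, with single-base forms of the site, with X and tRNA genes set against matched controls, of windows with several sites and of ranks in other lists were chosen after the data were seen. Of 248 alternative values, 215 did not reverse and kept their side of the threshold or, for counts without a test, stayed within 1.5 times. Many could hardly change (IDR of 0.01, where the deposited list ends, and gene lists with 0 peaks), so 215 does not measure robustness. Against flanking windows the site share was 6.92% in both, with no difference left. The enrichment near tRNA genes, at ribosomal protein genes and the overlap of the replicates' own lists passed under every alternative run for each, though the share near tRNA genes fell from 7.27 to 4.26% without replicate 2 (exact p = 0.0409). Leaving out a replicate leaves a shorter list made within the other, of 47 to 77 peaks, and an IDR of 0.005 left 156. Without 1 replicate the promoter share was 23.4 to 31.2% (not passing without replicate 2, exact p = 0.0943), the X share 25.5 to 26% (passing in neither), the signal difference of peaks with and without a site -2.97 to -2.61, the site distance relative to controls -43 to -13 bp (-7.5 bp in the full list), and the rank of the site 87 to 153. Ribosomal protein genes with a peak numbered 3 to 4 there and 6 at an IDR of 0.005 (10 in the full list), and Notch pathway genes 0 to 1 there and 1 with summits within 1000 bp of the gene start (3 in the full list). The 1 neuronal gene with a peak fell to 0, below expectation, with the pooled list, without either replicate, at an IDR of 0.005 and with summits within 1000 bp of the gene start, and the 1 heat shock gene to 0 without either replicate and with the nearest gene start only. With the pooled list the rank was 299, the site share 5.70% (below its controls), the median site distance 25 bp longer than in controls, the signal difference 8.06 (permutation p = 0.0484), windows with several sites 1.27% (exact p = 0.0620), and 2 intestinal genes had a peak. With the left-out entries kept, the site share was 10.8% (exact p = 0.0149) and the signal difference 14.4 (permutation p = 0.00702). These entries are mostly repeats, whose copies are not independent. The site share turned below its controls for TGGGAA (11.8%), TGRGAA (24.2%) and ATGGGAA alone (2.77%), with p from 0.149 to 0.582. It stayed above its controls without passing for GTGGGAA (4.50% against 3.01%, exact p = 0.160) and YRTGRGAA (7.96% against 6.44%, exact p = 0.319). With flanking windows as controls, windows with several sites (2.08%) no longer passed (exact p = 0.0923). With windows of 50 bp the E-box share was 37.0%, above its controls. With the nearest gene start only, 1 REF-1 family gene, hlh-29, had a peak, and at an IDR of 0.005 the Notch pathway count of 3 passed (permutation, adjusted p = 0.0213, range over its alternatives 0.0213 to 1). The causes of these changes were not tested. No paired analysis was possible because the series has 1 group. Depth is unknown, and at this number of peaks a site share of 10% was missed in some draws of the simulation, whose controls were not matched.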

Other observations

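All tests in this part were chosen only after the result was seen.

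Genes for small nuclear and nucleolar RNAs were close to many peaks, as tRNA genes were. Of the 289 summits 18 (6.23%, interval 3.98 to 9.63) lay within 500 bp of a snoRNA gene against 0.425% of background candidates, an odds ratio of 15.6 (Fisher exact test, 2-sided, adjusted p = 1.2e-14 over 8 gene classes), and 6 (2.08%) lay as close to an snRNA-class gene against 0.139% (odds ratio 15.2, adjusted p = 1.2e-05). Against controls matched on GC content and location the odds ratios were 7.92 and 15.3. The strongest peak of all, in pxn-1, lay 3 bp from the snoRNA gene ZK994.7, and other peaks lay over or beside sls-2.1 (116.4), sls-2.4 (97.9) and sls-2.2 (77.0), genes for the SL2 RNA that is trans-spliced onto messages from operons. Peaks near tRNA, snoRNA or snRNA genes numbered 44 (15.2% of all). The miRNA, rRNA and lincRNA classes did not pass (exact tests, adjusted p 0.306 to 1.0). Pseudogenes were near 11 peaks (3.81% against 5.00%, Fisher exact test, adjusted p = 0.478) and were less frequent than near matched controls (7.24%, odds ratio 0.507, adjusted p = 0.0449), and piRNA genes were near 1 peak (0.346% against 3.71%, odds ratio 0.0901, adjusted p = 8.9e-04; against matched controls 2.39%, odds ratio 0.142, adjusted p = 0.0373).

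Peaks on X often held GCGCAGGG, the core of the motif at sites that recruit the dosage compensation complex to X in hermaphrodites. It was present in 10 of 80 X peaks (12.5%, interval 6.93 to 21.5), in 25 of 24542 X candidates (0.102%) and in 1 of 209 autosomal peaks (0.478%), an odds ratio of 140.1 for X peaks against X candidates (Fisher exact test, 2-sided, p = 1.3e-17). The X peaks with the core included those nearest to W02H3.3 (162.6), F20B6.9 (137.7), gtr-1 (110.1), xol-1 (85.7), the X-dosage-sensitive switch gene of sex determination, and ins-39 (59.3). Of all peaks with the core 0 held a LAG-1 site. Over all 289 peaks the share was 6.92%, so 0 among so few peaks shows no lack of sites.

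Several LAG-1 sites close together were rare but more frequent in peaks. Windows with 2 or more sites made up 6 of 289 peaks (2.08%) and 14 of 2886 controls (0.485%), an odds ratio of 4.35 (1.36 to 12.2, Fisher exact test, 2-sided, p = 0.00698), and in 20 other draws of the controls p ranged from 3.1e-04 to 0.00904. The share was 4.26% in replicate 1's own list and 3.90% in replicate 2's (exact p = 0.0229 and 0.00271). Both own lists held the peak at sygl-1 and replicate 2's also that at lag-1, so these shares reuse peaks of the main list and are no separate test. With the left-out entries, which are mostly repeats, kept, the share was 6.94% (exact p = 5e-21). Copies of a repeat are not independent, and the controls were not matched on repeats, so this p does not measure evidence for clustered sites. The peaks were those at sygl-1 and lag-1 and those nearest to nspa-10 (7 sites in a fully masked repeat), Y43F8C.7, col-163 and tatn-1 (295 bp upstream). The windows at sygl-1 and lag-1 were 44.3% and 25.9% repeat-masked, and those at Y43F8C.7, col-163 and tatn-1 0%. The peak near Y43F8C.7 lay 28 bp from the snoRNA gene Y43F8C.22. A hypothesis is that closely spaced sites mark regions that LAG-1 occupies. Outside repeats the odds ratio was 4.70 (1.27 to 14.8), but this rests on 5 of the peaks that prompted the hypothesis and does not test it. With repeats included, the excess did not pass with flanking windows as controls or with the pooled list. In the 97 peaks of the other lists that touch no conservative region, 0 had 2 or more sites, against 2 of 970 matched controls (odds ratio 0, interval 0 to 53.4, Fisher exact test, 2-sided, p = 1.0), too few to decide. Among background candidates outside repeats, the median signal was 19.9 with 0 sites. It was 18.9 in the 288 with 2 sites, 21.1 in the 22 with 3 and 19.3 in the 6 with 4 or more. The background leaves out every called peak by construction, so these values cannot decide either, and the hypothesis stays open.

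A scan of all 3977 words of 8 bases found in at least 30 windows gave 9 words that passed adjustment, all more frequent in peaks, against 256 at an unadjusted p under 0.05. The first was CTCTCGGA (4.50% of peaks against 0.624% of controls, Fisher exact test, adjusted p = 0.00412), and GGGTTCGA (4.15% against 0.728%, adjusted p = 0.0105) is part of the internal promoter of tRNA genes.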
